A study of Mus musculus with 31 samples.

How the data were processed

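The series holds 31 libraries of 16S rRNA gene amplicons from mouse colon contents. Per the labels' protocols, microbial DNA was extracted with a stool kit, amplified by PCR, pooled in equal molar amounts and sequenced as paired reads of 300 bases on an Illumina NextSeq instrument. The primers, the denoiser, the taxonomy database and the rule that chose the listed ASVs are not given in the sources used here. A mouse genome build, mm10, is named in the submitters' processing notes and has no bearing on ASV counts.

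The authors deposited read counts per ASV and library in 2 tables, 16 ASVs over 12 libraries and 10 ASVs over 25 libraries. The 6 go-through-tube libraries are in both, and the 1 ASV that both list had equal counts in all 6. A column named as a percentage in the authors' deposited table holds a fraction of 1: in 16 of 16 ASVs it equals the ASV's summed count over 480358 reads, within 1e-08. The deposited p-value of each of the 16 ASVs, 0.00962 to 0.0453, is unadjusted, and its test is not named per the file headers. The second table has neither p-values nor taxonomy.

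Columns were matched to samples by the library name in the labels, and groups were taken from the sample titles. Replicates were tested for duplication by chi-square over the listed ASVs. All 81 library pairs of one group differed, with a largest chi-square p of 0.00056, and no library was counted as a copy of another. The test covers counting error only, so it cannot exclude a second amplification of the same sample. Pairs from different groups were not compared. The labels number the libraries as replicates and do not say which mouse or cage each came from, so p-values measure the spread between these libraries. PCR reads are not independent molecules, so floors cover counting error only.

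The planned test was edgeR's quasi-likelihood test with TMM scaling. Both tables list chosen ASVs, so scaling factors from them would follow the ASVs that differ. The reported fit therefore gives every library the same size of 40030 reads, the mean of the common total, with no scaling factor. This was decided after the files were seen and before any fit was run, and the planned fit is kept as an alternative. It called the same 5 ASVs for forced loss, and for ranks it called 6 ASVs that include all 5. An equal library size assumes equal depth, and the true depths were not used here. The common total covers the 12 libraries of the forced loss comparison only. Its mean was also used for the 25 libraries of the rank comparison, where Rank2 to Rank4 are outside that total.

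ASVs needed a summed count of at least 10 and reads in at least 4 libraries, which 16 of 16 and 10 of 10 met. The adjusted p threshold was 0.05 by Benjamini-Hochberg. For tests of ASVs between groups the adjustment ran over the listed ASVs only. It takes no account of ASVs that the authors may have tested and not listed. Values per group are means ± SD of reads. A fold against a group without a read is a lower bound against a floor of 3 counts per library, 0.00749% of the mean library total. Exact two-sided permutation tests used all splits of the 12 libraries, 462 when a split and its mirror count once. Tests across ranks used 100000 resamples. The lists of taxa were summed per library and tested the same way.

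The text names, for each test, up to 12 ASVs per direction with the smallest p among those that passed, or the 5 with the smallest p where fewer than 5 passed. It also names the 10 most abundant ASVs and, for each fixed list, the members that passed and the most abundant member. That rule, the lists, the tests and most alternatives were set before the data were examined. Under it all 16 and all 10 listed ASVs could be named.

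Planned tests of diversity, community composition, genera, families and phyla were not run, for either comparison, because chosen ASVs do not stand for whole communities or whole taxa. A further 6 lists held no listed ASV: lactic acid bacteria, mucin degraders, sulfate reducers, facultative anaerobes, reagent genera, and host and plant organelles.

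Alternatives were TMM, TMMwsp and the listed totals as library scale, DESeq2, limma on centred log-ratios with a pseudocount of 0.5, other filters, a replicate block, permutation tests and leaving out each library. Library totals fitted to the deposited p-values, in 8 searches, were added after seeing the data, as were the Kruskal-Wallis test and the Bacteroidales list without ASV3.

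The fitting code was tested on 50 simulated tables per comparison. For forced loss, with 16 ASVs per table, it called 6.00% of 4-fold and 33.7% of 16-fold changes, and 1.00% of unchanged ASVs. For ranks, with 10 ASVs per table, it called 11.0% of 4-fold and 22.4% of 16-fold changes, and 2.00% of unchanged ASVs. The simulated counts were negative binomial, with a spread fitted to the real counts, equal depth and no choice of ASVs by group. For ranks only Rank4 was changed. These rates therefore do not give the share of false calls among the listed ASVs. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.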

Results

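Bacterial 16S rRNA genes were sequenced from the colon contents of 31 male mice aged 6 to 8 weeks. The labels place 6 Rank1 mice under forced loss and 6 Rank1 mice under go-through-tube, and they add 7 mice of Rank2, 6 of Rank3 and 6 of Rank4. In the tube test of social dominance a pair of mice meets head-on in a narrow tube and one of them has to retreat. The labels name the treatments without a protocol for them. Values are reads per amplicon sequence variant (ASV, an exact 16S sequence standing for a bacterial strain or group of strains) and library, with each library taken as 1 mouse.

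The comparison of forced loss with go-through-tube has 16 listed ASVs and the comparison of ranks has 10. The listed ASVs held 1317 to 9132 reads per forced loss library and 882 to 2743 reads per go-through-tube library. In the rank comparison they held 86 to 793 reads per library. These sums are not library depths, because both tables list chosen ASVs. The fractions in the authors' deposited table refer to one common total of 480358 reads, a mean of 40030 reads for each of 12 libraries. The 16 ASVs made up 7.83% of that total, and 1.95% without ASV3.

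Forced loss was first set against go-through-tube in Rank1 mice, which asks how the treatment of a top-ranked mouse relates to its colon bacteria. The most abundant listed ASV was ASV3 of Alloprevotella, a gut genus of the Prevotellaceae, with 3800.3 ± 2626 reads under forced loss and 906 ± 638 under go-through-tube (SD, n = 6 each). Its mean was 4.20-fold higher under forced loss, yet it did not pass the edgeR test (log2 2.07, SE 1.12, adjusted p = 0.146, or 0.0327 without go-through-tube replicate 5). The fitted edgeR value of ASV3 fell to log2 1.40 with TMM (adjusted p = 0.231), 0.93 with TMMwsp (adjusted p = 0.542) and 0.46 with the listed totals (adjusted p = 0.738), and limma on centred log-ratios gave 3.16 (adjusted p = 0.0922). ASV2945, an unclassified member of the Lachnospiraceae, had reads in 4 of 6 forced loss mice and in 0 of 6 go-through-tube mice. ASV166 of the Lachnospiraceae NK4A136 group, ASV577 and ASV815 of unclassified Oscillospiraceae, and ASV614 of Oscillibacter had no read in any of the 6 forced loss mice. Those 4 ASVs had reads in 4, 4, 5 and 4 of the 6 go-through-tube mice.

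These 5 ASVs, each without a read in one whole group, were the ones that passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 1 higher and 4 lower under forced loss. ASV2945 averaged 36.8 ± 71.0 reads under forced loss (SD, n = 6), at least 12.3-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.0112). Its mean leaned on forced loss replicate 1 with 181 reads, and without that library the bound was 2.67-fold and the call was lost (edgeR adjusted p = 0.0553). ASV166 averaged 27 ± 32.7 reads under go-through-tube, at least 9-fold lower under forced loss (edgeR adjusted p = 0.0112), or at least 5.20-fold without go-through-tube replicate 2 with 84 reads. ASV815 averaged 22 ± 29.6 reads there, at least 7.33-fold lower under forced loss (edgeR adjusted p = 0.0112), or at least 3.67-fold without go-through-tube replicate 5 with 77 reads. ASV577 averaged 11.7 ± 12.8 reads there, at least 3.89-fold lower (edgeR adjusted p = 0.0290). ASV614 averaged 7.33 ± 8.19 reads there, at least 2.44-fold lower (edgeR adjusted p = 0.0458).

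An exact two-sided permutation test per ASV gave 9 of 16 unadjusted p-values under 0.05 and 0 of 16 after adjustment, with a smallest adjusted p of 0.0643. For an ASV without a read in one group that p depends only on how many mice of the other group had reads. It is 0.0606 for 4 of 6 mice, so ASV2945, ASV166, ASV577 and ASV614 could not pass the exact test, and 0.0152 for ASV815. Leaving out each library in turn kept ASV166 and ASV815 in 12 of 12 fits, ASV2945 in 11, ASV577 in 6 and ASV614 in 1. The number of calls was 2 without forced loss replicate 1, 3 without forced loss replicate 2, 5 or 6 or go-through-tube replicate 4 or 6, and 7 without go-through-tube replicate 2. The ASVs were listed with p-values under 0.05 on these same mice, so their differences are not independent evidence. The adjusted p-values cover the 16 listed ASVs only, so they do not bound the share of false calls.

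**Figure D1:**
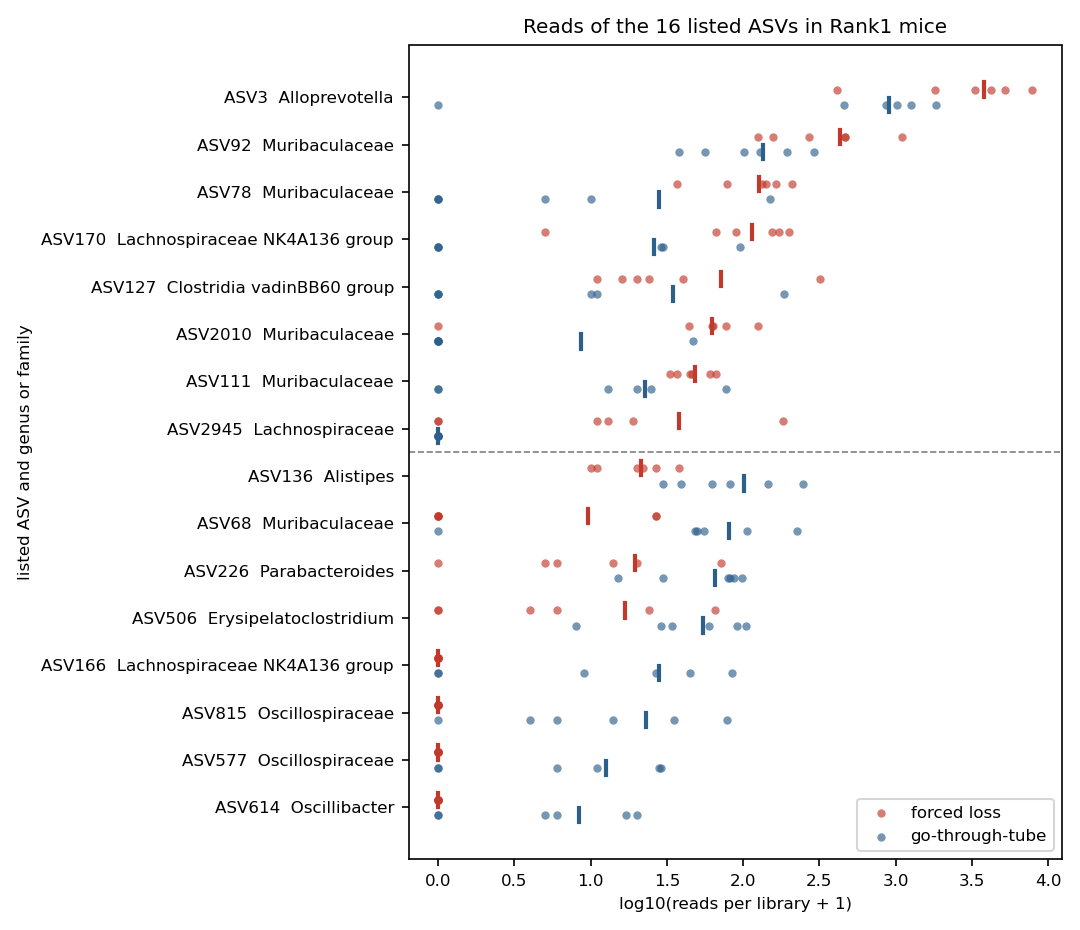
Reads of the 16 listed ASVs on an axis of log10(reads per library + 1), with one point per mouse (6 forced loss, 6 go-through-tube) and a vertical bar at each group mean. ASVs above the dashed line have the higher mean under forced loss; ASV2945 has no read under go-through-tube, and ASV166, ASV815, ASV577 and ASV614 have none under forced loss. ASV111 and ASV127 move to the other side of the line when TMMwsp or the listed totals set the library scale, ASV111 also under DESeq2 and ASV127 also under TMM and without forced loss replicate 4.

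Muribaculaceae, the family of Bacteroidales that is often abundant in the mouse gut, contributed 5 listed ASVs, of which 0 passed. ASV92 averaged 430 ± 361 reads under forced loss and 134 ± 95.3 under go-through-tube (edgeR adjusted p = 0.146), and its log2 value of 1.68 fell to 0.0376 with the listed totals. ASV78 averaged 126 ± 61.3 and 27.2 ± 60.3 reads, present in 6 of 6 and 3 of 6 mice (edgeR adjusted p = 0.188, or 0.00189 without go-through-tube replicate 2; DESeq2 0.0354). ASV2010 averaged 61.2 ± 40.9 and 7.67 ± 18.8 reads, present in 5 of 6 and 1 of 6 mice (edgeR adjusted p = 0.146, or 0.000359 without go-through-tube replicate 2). ASV111 averaged 47.0 ± 13.1 and 21.8 ± 28.3 reads, a direction that reversed when the listed totals, TMMwsp or DESeq2 set the library scale. ASV68 ran the other way, with 8.67 ± 13.4 reads under forced loss and 80.0 ± 78.5 under go-through-tube (log2 -3.19, SE 1.61, edgeR adjusted p = 0.136), with log2 -4.77 under the listed totals (edgeR adjusted p = 0.0128) and -2.54 without go-through-tube replicate 2.

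The other Bacteroidales were Alistipes of the Rikenellaceae and Parabacteroides of the Tannerellaceae, both common bile-tolerant gut anaerobes. ASV136 of Alistipes averaged 20.3 ± 10.5 reads under forced loss and 100 ± 82.6 under go-through-tube (log2 -2.29, SE 1.07, edgeR adjusted p = 0.116), and it passed by DESeq2 (adjusted p = 0.0105) and with the listed totals (edgeR adjusted p = 0.0143). It had the smallest exact permutation p of the 16 ASVs, 0.00433, with an adjusted exact p of 0.0643. ASV226 of Parabacteroides averaged 18.5 ± 26.1 and 64.2 ± 34.0 reads (log2 -1.79, edgeR adjusted p = 0.202), and it passed with the listed totals (log2 -3.50, edgeR adjusted p = 0.0434). Without forced loss replicate 6 with 70 reads its log2 value was -2.95 (edgeR adjusted p = 0.0955). The listed totals averaged 4748 reads under forced loss and 1521 under go-through-tube, and most of these reads were ASV3. As library size they lowered most log2 values (median change per ASV -1.40). The passes of ASV68, ASV136 and ASV226 with the listed totals therefore cannot be told apart from the difference in ASV3.

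By limma on centred log-ratios 12 ASVs passed, among them ASV78, ASV2010, ASV68, ASV136, ASV226, ASV170 and ASV506.

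Among Firmicutes that did not pass by edgeR, ASV170 of the NK4A136 group averaged 113 ± 73.3 reads under forced loss and 25.2 ± 36.5 under go-through-tube (edgeR adjusted p = 0.188), and its log2 value of 2.16 fell to 0.43 with the listed totals and rose to 3.30 without go-through-tube replicate 5 with 94 reads (edgeR adjusted p = 0.0913). The other listed member of that genus was ASV166, absent under forced loss, so the genus held ASVs of both directions. ASV506 of Erysipelatoclostridium averaged 15.8 ± 25.1 and 53.3 ± 37.5 reads (log2 -1.74, edgeR adjusted p = 0.246). Without forced loss replicate 5 with 64 reads its log2 value was -3.08 (edgeR adjusted p = 0.123). ASV127 of the uncultured Clostridia vadinBB60 group averaged 70.3 ± 121 and 33.8 ± 73.7 reads, a direction that reversed under TMM, TMMwsp and the listed totals and without forced loss replicate 4.

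By group mean, 5 of 8 listed Bacteroidota and 3 of 8 listed Firmicutes were higher under forced loss, counts that include ASV111 and ASV127, whose direction reversed under other scalings. A difference in direction between the phyla was not detected (Fisher's exact p = 0.619). That test counts ASVs as independent, though they come from the same mice and were chosen on them. Its p therefore measures no spread between mice and cannot decide the question. Of the Oscillospiraceae, 3 of 3 listed ASVs were lower.

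Of 9 taxon lists fixed before the data were examined, 3 held a listed ASV. The Bacteroidales list held 8 ASVs, and their summed reads averaged 4512 ± 2790 under forced loss and 1341 ± 714 under go-through-tube (n = 6 each, exact permutation p = 0.0260, adjusted 0.0779). Without ASV3, the other 7 summed to 712 ± 465 and 435 ± 151 reads (exact permutation p = 0.171). The list of short-chain fatty acid producing Clostridia held ASV170, ASV166 and ASV614, with sums of 113 ± 73.3 and 59.5 ± 48.5 reads (exact permutation p = 0.171, adjusted 0.171). The Erysipelotrichales list held ASV506 alone (exact permutation p = 0.0693, adjusted 0.104). Members past the edgeR threshold numbered 0 of 8, 2 of 3 and 0 of 1, against 5 of 16 over all listed ASVs. They were again 0, 2 and 0 when adjusted over the list alone. The 2 Clostridia, ASV166 and ASV614, were lower under forced loss, where the higher sum came from ASV170 alone. The Bacteroidales sum passed without forced loss replicate 1 (exact permutation, adjusted p = 0.0260), and the 3 lists all passed without forced loss replicate 5 (adjusted p = 0.0476, 0.0325 and 0.0260 for Clostridia, Bacteroidales and Erysipelotrichales). The study chose these ASVs on these samples, so the lists are not independent evidence of a direction.

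The 4 ranks were compared with go-through-tube mice as Rank1. The titles of Rank2 to Rank4 mice name no treatment. A difference between Rank1 and the other ranks therefore cannot be told apart from one of the go-through-tube treatment. The 10 listed ASVs carry no taxonomy in this table, and ASV614 takes its genus from the other comparison. ASV91 averaged 178.5 ± 262 reads in Rank4 (n = 6), with reads in 5 of 6 mice, and had none in the 6 Rank3 mice, at least 59.5-fold more in Rank4. Of its 1071 reads in Rank4, 670 came from replicate 5, and without that mouse the bound was 26.7-fold. Rank2 mice averaged 40.0 ± 51.1 reads of ASV91 (n = 7) and Rank1 mice 1.67 ± 4.08. ASV641 averaged 34.0 ± 34.4 reads in Rank2 and 5.50 ± 8.57 in Rank1, and it had none in Rank3 and Rank4. ASV614 of Oscillibacter averaged 7.33 ± 8.19 reads in Rank1 and had none in Rank2 and Rank4; the Rank3 mean of 11.7 ± 28.6 came from 1 mouse with 70 reads.

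ASV2380 and ASV694 were sparse. ASV2380 averaged 4.83 ± 6.08 reads in Rank1 and 4.17 ± 4.79 in Rank3, and it had none in Rank2 and Rank4. Rank1 replicate 5 held 15 of its 29 Rank1 reads, and without it the Rank1 mean was 2.80, below the floor of 3 counts. ASV694 averaged 8.33 ± 8.45 reads in Rank3 against 1.5 ± 3.67 in Rank1, 0.286 ± 0.756 in Rank2 and none in Rank4. ASV91, ASV641, ASV614, ASV2380 and ASV694 passed the edgeR quasi-likelihood test over ranks, with adjusted p-values of 2.5e-05, 0.000472, 0.00181, 0.00597 and 0.0141. Each had at least 1 rank without a read. Leaving out each library in turn kept all 5 in 25 of 25 fits, but DESeq2 called 1 of the 10 ASVs, ASV91. By limma on centred log-ratios ASV91 and ASV641 passed, and ASV614, ASV2380 and ASV694 did not (adjusted p = 0.130, 0.305 and 0.306).

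The more widely carried ASVs did not pass. ASV25 averaged 158 ± 174, 175 ± 97.1, 137 ± 81.7 and 29.3 ± 50 reads in Rank1 to Rank4, with reads in 5 of 6, 7 of 7, 6 of 6 and 2 of 6 mice (edgeR adjusted p = 0.469). ASV46 averaged 70.2 ± 108, 167 ± 71.1, 162 ± 76.7 and 81.5 ± 52.4 reads (edgeR adjusted p = 0.752). Without the library with most reads in each rank, ASV25 averaged 98, 156, 114 and 11 reads and ASV46 30.8, 153, 137 and 71.4. ASV774 had its highest mean in Rank3, 37.7 ± 24.8 reads (edgeR adjusted p = 0.643), as did ASV648 with 33.7 ± 21.9 reads (edgeR adjusted p = 0.285). ASV621 averaged 30.3 ± 60.4 reads in Rank1 and 0.571 ± 1.51 in Rank2 (edgeR adjusted p = 0.0913). Rank1 replicate 1 held 153 of its 182 Rank1 reads, and without it the Rank1 mean was 5.80, below the Rank4 mean of 14.3 ± 12.2 (edgeR adjusted p = 0.276). ASV621 passed with TMM scaling (edgeR adjusted p = 0.00979) and without Rank2 replicate 4 (edgeR adjusted p = 0.0177). It also passed with TMMwsp, with the listed totals and by limma on centred log-ratios. Among ASVs present in at least a share of 0.5 of the libraries, it was the only call. That filter left 4 ASVs and removed the 5 that passed the reported fit. ASV648 passed without Rank4 replicate 1 (edgeR adjusted p = 0.0278), and limma on centred log-ratios passed ASV25 (adjusted p = 0.00511) and ASV46 (adjusted p = 0.0142).

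A Kruskal-Wallis permutation test on the counts, chosen after seeing the data, passed 10 of 10 ASVs with adjusted p-values of 0.0377 to 0.0435. The table holds only chosen ASVs, so the differences are not independent evidence. By the asymptotic Kruskal-Wallis test, without permutation, 9 of 10 had an unadjusted p under 0.05 and the highest was 0.0520. No ASV followed rank order after adjustment by a permutation test of Spearman's rho, and 1 did before it, ASV614 (rho = -0.461, permutation p = 0.0210, adjusted 0.179).

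**Figure D2:**
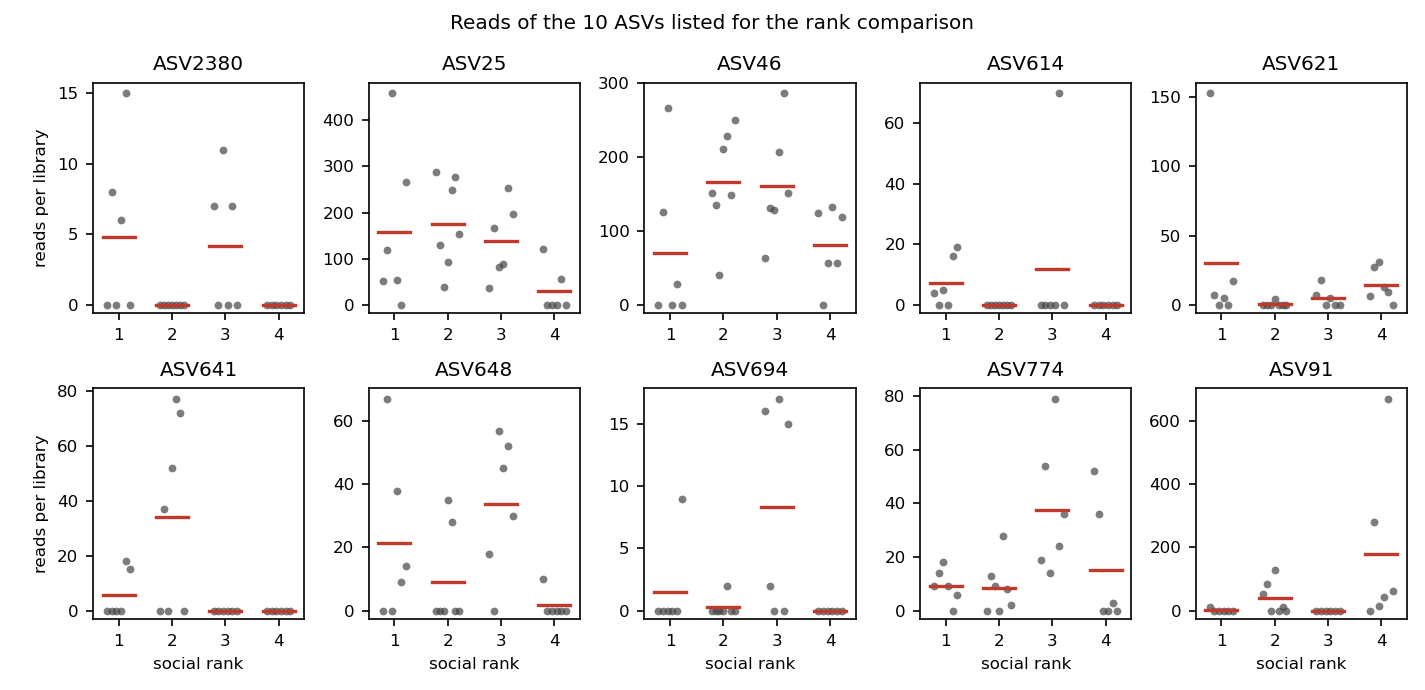
Reads per library of the 10 ASVs listed for the rank comparison, one panel per ASV with its own linear axis, against social rank on the horizontal axis (6, 7, 6 and 6 mice for Rank1 to Rank4). Points are mice and horizontal bars are group means. Rank1 mice are the go-through-tube mice. ASV641 has no read in Rank3 and Rank4, and ASV91 is highest in Rank4.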

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

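All tests weighed in this part were chosen after their results were seen. A gap test on each ASV and group placed 17 of 58 groups with 1 library far above the rest. Chance places about 1 in 20 groups there if values are normal, which counts with many zeros are not, and 7 of the 17 met the test by construction because every other library was at 0 reads. In forced loss mice the libraries were replicate 6 for ASV92 (1104 reads) and ASV226 (70 reads), replicate 4 for ASV127 (316 reads), replicate 5 for ASV506 (64 reads) and replicate 1 for ASV2945 (181 reads). In go-through-tube mice of the same comparison they were replicate 2 for ASV78 (150 reads) and ASV2010 (46 reads), replicate 5 for ASV170 (94 reads) and ASV127 (184 reads), and replicate 3 for ASV111 (76 reads). In the rank comparison, Rank1 replicate 1 stood apart for ASV621 (153 reads) and ASV91 (10 reads), and Rank1 replicate 6 for ASV694 (9 reads). Rank2 replicate 4 stood apart for ASV621 (4 reads), Rank2 replicate 5 for ASV694 (2 reads), Rank3 replicate 5 for ASV614 (70 reads) and Rank4 replicate 1 for ASV648 (10 reads).

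The first pattern weighed was the set of 4 ASVs without a read in any forced loss library, ASV166, ASV577, ASV614 and ASV815. A lower depth of those libraries would give 0 reads with a probability of 0.05 at a depth ratio of at most 0.0185 for ASV166, 0.0428 for ASV577, 0.0227 for ASV815 and 0.00823 for these 3 together. The reads listed for forced loss force a ratio of at least 0.0630, which argues against depth as the cause for these 3 as far as counting error goes, but for ASV614, at 0.0681, lower depth cannot be excluded. Patchy carriage between mice together with the choice of listed ASVs may account for them and stays open, because 16 unadjusted p-values under 0.05 arise by chance from 320 tests, ASV numbers reach 2945, and the number of ASVs tested is not given in the sources used here. An effect of forced loss itself stays open beside it.

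Other splits of the libraries gave fewer calls than the real groups. For forced loss 1 of 100 splits, the real one, gave 5 calls and the highest other gave 2. Across ranks 1 of 100 regroupings, the real one, gave 5 calls and the highest other gave 4. Chance cannot be excluded by either count, because the ASVs were chosen on the real groups.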

How the results depend on the processing

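TMM was the scaling of the planned test; library totals fitted to the deposited p-values and the Kruskal-Wallis test were added after seeing the data, and the other alternatives here were planned. For forced loss, where edgeR called 5 ASVs, calls numbered 8 with the listed totals as library size, 12 by limma on centred log-ratios (4 higher and 8 lower, against 1 and 4), 0 with ASVs present in at least a share of 0.5 of the libraries, and 0 by permutation test, which 4 of the 5 could not pass. The stricter prevalence filter removes the 5 called ASVs by construction; it left 11 ASVs, 2 of them with an unadjusted p under 0.05. TMM called 5, TMMwsp 6 and DESeq2 7, each including the same 5 ASVs. The fitted totals of smallest spread called the same 5, and those of the other 7 searches 4 to 5; ASV614 was lost with 1 of them (adjusted p = 0.0522). Leaving out 1 library gave 2 to 7 calls: 2 without forced loss replicate 1, 3 without forced loss replicates 2, 5 or 6 or go-through-tube replicates 4 or 6, and 7 without go-through-tube replicate 2. The change in log2 value from the reported fit, taken per ASV, had a median of -0.44 under TMM and -1.40 under the listed totals. That median was -0.88 under TMMwsp and 1.57 under centred log-ratios, where single ASVs moved in both directions. ASV111 reversed to -0.21 under the listed totals, -0.58 under TMMwsp and -0.0914 under DESeq2. ASV127 reversed to -0.0183 under TMM, -1.44 under the listed totals, -0.0693 under TMMwsp and -0.67 without forced loss replicate 4, with -0.67 to 4.17 over the libraries left out. Across ranks, where edgeR called 5, calls numbered 1 by DESeq2, 10 by Kruskal-Wallis permutation test and 5 by centred log-ratios (2 of the same). They numbered 6 by TMM, TMMwsp or the listed totals, and 5 to 6 without 1 library. The stricter prevalence filter left 4 ASVs with 1 call, and it removed the 5 called ASVs before any test. Of the lists, 0 passed, with 0 to 3 without 1 library: 1 without forced loss replicate 1 and 3 without forced loss replicate 5. Apart from the filter, the cause was not tested. Using no filter removed nothing and tests nothing.

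With the replicate number as a replicate block, calls numbered 0 for forced loss (4 ASVs with an unadjusted p under 0.05; adjusted p-values of the 5 from 0.240 to 0.558), 2 across ranks (ASV614, ASV2380 and ASV694 at 0.0516, 0.0697 and 0.110) and 0 of the lists. The labels do not say that a number marks shared mice or days. In the forced loss comparison same-numbered libraries had a mean correlation of -0.00053 (exact one-sided p = 0.514). Across ranks it was -0.0596 (permutation p = 0.856). With so few libraries and only chosen ASVs, these values cannot tell whether a number marks a shared cage or handling. The reported fits leave the numbers out because the labels name no pairs. Pairing therefore stays open, and the calls depend on that choice. The depth of each library was not used here, which limits all values to reads and not shares of a library.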

Other observations

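All tests in this part were chosen after their results were seen. ASV614 of Oscillibacter was the 1 ASV listed in both comparisons, and over the 31 libraries it had reads in 4 of 6 go-through-tube Rank1 mice, 0 of 6 forced loss Rank1 mice, 0 of 7 Rank2, 1 of 6 Rank3 and 0 of 6 Rank4 mice. Fisher's exact test gave p = 0.00548 for go-through-tube Rank1 against Rank2 to Rank4, and p = 0.0606 against forced loss. It was singled out after its values were seen, and both comparisons use mice on which it was listed. Against Rank2 to Rank4, being Rank1 cannot be told apart from the go-through-tube treatment.

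The deposited p-values of the 16 ASVs were set against tests on the counts. In the authors' deposited table they run from 0.00962 to 0.0453. A rank-sum test with continuity correction on the counts gave 8 of 16 to 4 digits, among them 5 of 5 ASVs absent from one whole group, and put 4 ASVs at or above 0.05. A candidate explanation is a rescaling of each library before the authors' test: 16 of 16 deposited p-values came out in 8 of 8 searches for library totals. The totals are not determined, since the highest was 1.33-fold to 4.92-fold the lowest and the search favoured near-equal ones. The fit has 12 free totals for the 8 unmatched values, so its match is weak evidence for a rescaling. The order between groups of the 5 of 5 ASVs cannot be altered by any rescaling. Their match bears on the rank-sum test and cannot test a rescaling. Another test on the same counts is argued against only for the 5 others tried, of which the best gave 0 of 16. Further tests were not tried.

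ASV78 and ASV2010, both Muribaculaceae, varied together between forced loss mice (r = 0.945, exact permutation p = 0.00833; rho = 0.829, exact permutation p = 0.0583; n = 6), and r was 0.759 without the 2 mice farthest from the median. Over the 171 pairs tested the adjusted p was 0.475, so the relation did not hold after adjustment. In go-through-tube mice ASV166 with ASV68 (r = 0.962) and ASV170 with ASV127 (r = 0.946) had the same adjusted p by this test. A hypothesis is that ASV78 and ASV2010 are 2 copies of one genome in a fixed ratio. Over the 9 libraries with reads of either, a permutation test of equal shares gave p = 2e-05 and at most 0.00311 without any 1 library, which argues against a fixed ratio. ASV2010 had 0 of 36 reads in forced loss replicate 5, and 0 of 4 and 0 of 9 in go-through-tube replicates 5 and 6. The 6 libraries with reads of both, chosen by that outcome, ran from 23.5% to 37.5% (permutation p = 0.0094). The test covers counting error only, so extra spread from PCR or denoising was not tested.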
